A study of Paraburkholderia phymatum STM815 with 6 samples.

How the data were processed

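RNA was extracted from flash-frozen planktonic cells with hot phenol and made into libraries with a kit for prokaryotic RNA, per the labels' protocols. The deposited files hold, for each of 7899 gene entries, a count of reads mapped to 1 place, a count of all mapped reads, and an RPKM value, per the file headers. The RPKM column was computed by the authors from the count of all mapped reads, and it equals that count divided by gene length and by the sum of that count in the library, checked on every entry. It was not tested further. DESeq is named in the submitters' processing notes, with no version or role. The mapper, the genome build, read filters and strand handling are not given in the sources used here. Without strand information, reads of overlapping or antisense genes cannot be told apart. Genes with near-identical copies lose reads in the count of reads mapped to 1 place and are described as uncertain.

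The files name 360 entries by gene symbol and 7539 by locus tag, and do not pair the tags with names or products. Only 2 tags of lower genes and 2 of higher genes are printed, and other such genes are given by position. The sequence records in the files are called chromosome 1, chromosome 2, pBPHY01 and pBPHY02, names assigned from general knowledge of this strain's genome. No genome or annotation was used. For that reason the level of rpoN itself, as a check of the mutant label, and the σ54 promoter motif upstream of lower genes are not analysed here. The same holds for gene lists that rest on products.

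The 81 entries of RNA genes (tags of RNA genes and ffs) were left out of library sizes and tests. They took 55.2 to 56.2% of all mapped reads in the wild type and in mutant 1, 61.7% in mutant 2 and 64.1% in mutant 3, but 0.164 to 0.206% of reads mapped to 1 place. The count of reads mapped to 1 place was tested, a choice made after the columns were seen and before any test was run. It came to 11534704 to 12618911 per wild-type library and 6442577 to 12989717 per mutant library, RNA genes included. A count of 0 is reported with the CPM that 3 counts would give. Intervals of read shares, and floors, cover counting error only.

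The groups come from the sample titles. The labels do not say whether the replicates came from separate cultures. Their optical densities set wild type 1 apart from wild type 2 and 3 and do not separate the other libraries, so p-values measure the spread between these samples, part of which may be technical. Libraries of a group differed by more than sampling noise (chi-square per degree of freedom 7.22 to 28.8), and none was counted as a duplicate. On the first principal component, with 62.9% of the variance, wild type and mutant separated, and on the second (11.2%) mutant 1 stood apart from mutant 2 and 3. The replicate numbers were not treated as pairs. The later file date is shared by mutant libraries only, so that a fit with the date as a term rests on mutant 1 for the comparison with the wild type. The lower optical density is shared by wild-type libraries only. A fit with the density as a term thus compares the mutant with wild type 1.

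Counts were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM scaling, robust quasi-likelihood fit and test, two-sided, Benjamini-Hochberg adjusted p under 0.05). Of 7818 genes 7517 were tested, and 301 fell under the filter. The common biological coefficient of variation was 0.142. Standard errors are the log2 fold change divided by the square root of the F statistic. Gene lists were tested with camera from limma 3.58.1 (preset correlation 0.01, lists of at least 5 tested members, 11 lists). Of the 30 lists fixed before the data were examined, 10 had members by symbol, 19 had none and are not analysed here, and that of ribosomal proteins was replaced by symbols. The 11 lists built from the symbols in the files, that of ribosomal proteins included, were written after the names in the files were seen and before any test was run. Replicons were compared with Fisher's exact test. Runs of neighbouring genes were compared with 1000 permutations of the calls over the tested genes. Figures were drawn with matplotlib 3.10.9.

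The rule for named genes was fixed before the data were examined. It took the σ54 gene itself, which is not analysed here, and, among genes with an adjusted p under 0.05, a mean of at least 10 CPM and no overlap of the groups, the 8 with the lowest and the 6 with the highest log2 fold change, and of each list with at least 2 called genes the 2 with the lowest adjusted p (4 for flagellar genes, and for 3 lists without members here: chemotaxis, dicarboxylate transport and type VI secretion). It gave 36 genes. Any other gene given by name was chosen after its value was seen, also where the text does not repeat this.

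The alternatives were a replicate block, the file date or the optical density as a term, RLE, upper quartile and library total scaling, other filters, DESeq2 1.42.0, limma voom, RNA genes kept, each library left out in turn, and a stricter adjusted p. For gene lists an estimated correlation and fry were used. All mapped reads, the first file date alone, counts thinned to the smallest library and genes of at least 300 bases were chosen after seeing the data. The test was run on simulated counts with known changes over 7469 genes, for the comparison of mutant with wild type. Of the simulated genes 67, 67 and 66 were changed 1.5-fold, 2-fold and 4-fold, a far smaller share than the 26.3% called in the data. The test recovered 44.8% of genes changed 1.5-fold, 71.6% of those changed 2-fold and 97.0% of those changed 4-fold. Adjustment is stricter where fewer genes change, so these shares do not give the power of the real comparison. Of 154 calls 12 were false (7.79%), and 1 gene was called where none had been changed.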

Results

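Paraburkholderia phymatum STM815 is a soil bacterium that nodulates legumes, and rpoN encodes σ54, an alternative sigma factor that directs RNA polymerase to a particular class of promoters. Gene expression was measured by RNA sequencing in free-living planktonic cells of the wild type (3 libraries) and of an rpoN mutant (3 libraries). All cells had gone through a shift of minimal medium from 15 to 0.3 mM ammonium. The optical density (OD600) on the labels was 0.6 for wild type 1 and for the 3 mutant libraries, and 0.5 for wild type 2 and 3. The comparison asks which genes depend on rpoN outside the plant host. Reads mapped to 1 place in the genome numbered 11534704, 12291106 and 12618911 in wild type 1, 2 and 3, and 12989717, 6442577 and 6722884 in mutant 1, 2 and 3. The 3 wild-type files and that of mutant 1 carry the same date, and those of mutant 2 and 3 a later one. The replicon, start and end of each gene are given as in the deposited files.

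Loss of rpoN was accompanied by lower transcript levels of every flagellar gene that carries a name in the files, by lower levels of most ribosomal protein genes, and by higher levels of the chaperone genes groES, groEL and dnaK. Of 7517 genes tested, 929 were higher and 1049 lower in the mutant (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), which is 26.3% of the genes. Changes of at least 2-fold were more often decreases, with 376 genes lower and 111 higher. The CPM values of the groups did not overlap for 3020 genes (40.2%, where chance gives 10%). With library totals in place of TMM scaling, 694 genes were higher and 1214 lower, so that decreases made up 63.6% of the calls against 53.0%. The majority turned with RLE scaling (1000 higher and 981 lower), with DESeq2 (987 and 961) and without mutant 3 (802 and 782). Within the libraries of the first file date, where the mutant is a lone sample assumed to vary like the wild type, 450 genes were higher and 459 lower. With the file date as a term the counts were 509 and 544, and with the optical density as a term 549 and 605. The former comparison rests on mutant 1 and the latter on wild type 1. Calls lost there do not by themselves show an effect of date or density.

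Most of the largest decreases lay in short stretches of neighbouring genes on chromosome 2 and on the replicon pBPHY01. Bphy_5667 (pBPHY01, 152324 to 153688) had 2813 ± 396 CPM in the wild type (SD, n = 3) and 15.5 ± 0.645 in the mutant (SD, n = 3), a log2 fold change of -7.50 (SE 0.15, edgeR adjusted p = 4.1e-19). The next genes downstream, at 153762 to 155633 and at 155623 to 156987, had log2 fold changes of -5.81 and -4.94. Bphy_3960 (chromosome 2, 934938 to 935735) went from 2979 ± 592 CPM (SD, n = 3) to 17.5 ± 0.129 (SD, n = 3), a log2 fold change of -7.41 (SE 0.16, edgeR adjusted p = 3.2e-18). Its neighbours at 933883 to 934893 and at 935760 to 936623 had log2 fold changes of -7.16 and -6.09, the former from 8409 to 58.8 CPM. A gene of 339 bases on chromosome 2 (2437189 to 2437527) had a log2 fold change of -5.06, and a gene on chromosome 1 (248341 to 249621) one of -4.86. These 8 genes kept their direction and their calls in each fit that left out a library.

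The largest increases were on pBPHY01. Bphy_6013 (552375 to 555062) rose from 449.6 ± 298 CPM (SD, n = 3) to 15318 ± 491 (SD, n = 3), a log2 fold change of 5.09 (SE 0.84, edgeR adjusted p = 0.0163). The adjacent Bphy_6014 (555073 to 556371) rose from 162 ± 107 CPM to 5262 ± 299, a log2 fold change of 5.02 (SE 0.83, edgeR adjusted p = 0.0167). Wild type 2 stood low for both, with 112 CPM of Bphy_6013 against 676 and 560 in wild type 1 and 3, and without it the adjusted p of Bphy_6013 was 6.0e-17. The call for Bphy_6013 was lost without mutant 2 (adjusted p = 0.0563), mutant 3 (0.0547) or wild type 3 (0.0685). That for Bphy_6014 was lost without mutant 2 (0.0580), mutant 3 (0.0551), wild type 1 (0.0533) or wild type 3 (0.0662). Both were also lost with the file date as a term (adjusted p = 0.0811 and 0.0827), with the optical density as a term (0.159 and 0.166) and within the first file date (0.187 and 0.188). Their log2 fold changes lay between 4.49 and 5.06 in these fits and between 4.57 and 5.51 without single libraries. Further along, 3 consecutive genes between 568257 and 570854 had log2 fold changes of 4.13, 3.99 and 3.54, from wild-type means of 2.47, 5.43 and 2.28 CPM. On chromosome 1, a gene at 1188289 to 1189719 rose from 208 ± 29.6 to 1872 ± 143 CPM (SD, n = 3 in each group), a log2 fold change of 3.17.

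All 21 flagellar genes named in the files, which encode parts of the basal body, rod, hook, export apparatus, stator and their regulators, were lower in the mutant. The median log2 fold change was -3.33, a 10.03-fold decrease, and single genes lay between -4.62 and -1.62. The rod protein gene flgJ (chromosome 1, 3308721 to 3309653) fell from 29.5 ± 8.32 to 3.99 ± 1.03 CPM (log2 fold change -2.93, SE 0.25, edgeR adjusted p = 1.8e-08, n = 3 in each group). The stator gene motB (3334463 to 3335572) fell from 60.3 ± 15.5 to 15.0 ± 0.818 CPM (log2 fold change -2.00, edgeR adjusted p = 2.3e-08). The export genes fliH and flhA had log2 fold changes of -2.50 and -1.62. Named here after its value was seen, the rod gene flgC had the lowest log2 fold change with all libraries, -4.62, and -3.94 without wild type 2. fliA, which encodes the flagellar sigma factor and was also named after its value was seen, fell by 2.70. Without wild type 2 it was at -2.24. The count was also 21 when adjusted over the list alone. The list stood apart from other genes in camera (adjusted p = 6.7e-30 over 11 lists) but not with an estimated correlation (adjusted p = 0.447 with an estimated correlation). Wild type 2 exceeded wild type 1 and 3 in all 21 genes, by a median of 1.91-fold, and without wild type 2 all 21 genes were still called, with a median of -2.97. Within the first file date, where the mutant is a lone sample, 9 of the 21 were called and the median was -3.26. With the file date as a term 17 were called, with a median of -3.28. The flgC call was lost in both fits (adjusted p = 0.214 and 0.107), at log2 fold changes of -4.57 and -4.58, and that of fliA within the first file date (0.0870), at -2.19.

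**Figure D1:**
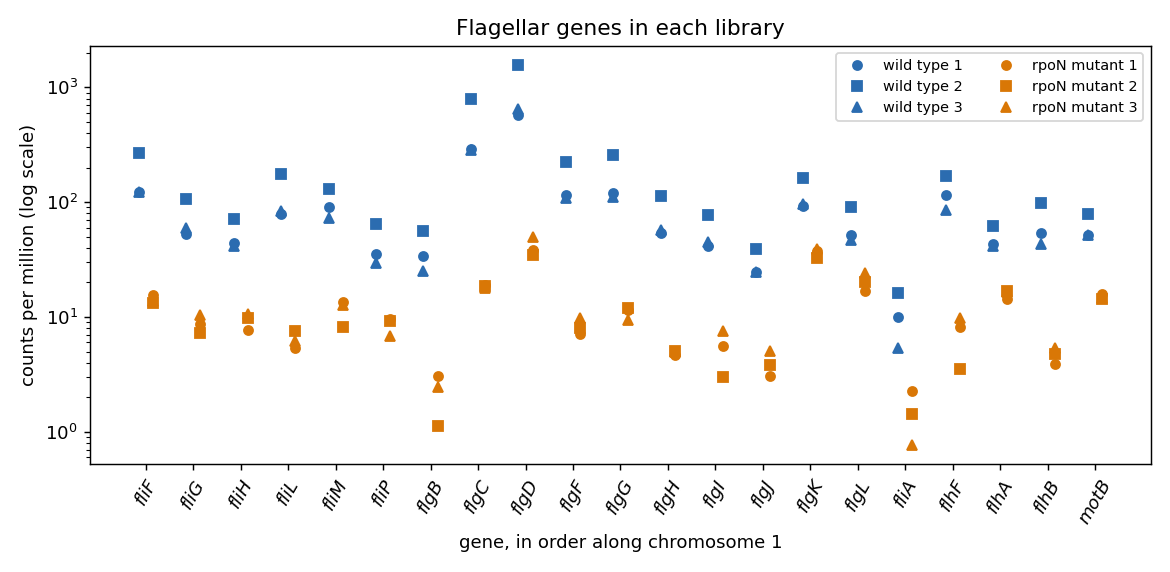
CPM (log axis) of the 21 flagellar genes named in the files, in their order along chromosome 1, with each marker standing for 1 library of the wild type (blue) or the rpoN mutant (orange). In every gene the 3 wild-type libraries lie above the 3 mutant libraries, and wild type 2 lies highest.

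Ribosomal protein genes, a list assembled from the names in the files, were lower in the mutant in 41 of 49 cases, with 1 gene higher and 7 not called. Adjusted over the list alone, 42 were lower and 1 higher. The median log2 fold change was -0.68, a 1.60-fold decrease. The large-subunit genes rpmI and rplJ both fell by 0.98 on the log2 scale, rpmI from 610 ± 58.3 to 309 ± 36.6 CPM and rplJ from 158 ± 21.2 to 80.3 ± 3.92 CPM (SD, n = 3 in each group; edgeR adjusted p = 6.7e-07 and 1.6e-06). The exception, named after its value was seen, was rpsU_2 on chromosome 2, with a log2 fold change of 0.40, and that call was lost with the file date as a term (adjusted p = 0.113), within the first file date (0.149) and with the optical density as a term (0.0783), at log2 fold changes of 0.33, 0.34 and 0.36. Within the first file date 28 ribosomal protein genes were called lower, with a median of -0.65 over the list. Camera placed the list below other genes (adjusted p = 3.5e-14), a call that was lost with an estimated correlation (adjusted p = 0.447 with an estimated correlation). The gene rpmJ, of 117 bases, had 953, 952, 1067 and 932 reads in the libraries of the first date and 0 reads in mutant 2 and 3, which allows up to 0.477 and 0.463 CPM there, and was not called.

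The 3 chaperone genes named in the files were higher in the mutant, also when adjusted over the list alone. The chaperonin gene groES (chromosome 1, 2617578 to 2617868) rose from 457 ± 21.2 to 1405 ± 196 CPM (SD, n = 3 in each group), a log2 fold change of 1.62 (SE 0.11, edgeR adjusted p = 3.5e-10). Its partner groEL rose from 5631 ± 940.2 to 11977 ± 845 CPM, a log2 fold change of 1.09 (SE 0.12, edgeR adjusted p = 1.1e-06). dnaK, which encodes another chaperone and was named after its values were seen, rose by a log2 fold change of 0.92. All 3 were called within the first file date and in each fit that left out a library.

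In central carbon metabolism, 4 of 11 genes of the tricarboxylic acid cycle were higher, 1 was lower and 6 were not called (5 higher and 1 lower when adjusted over the list alone). The list was written for the glyoxylate cycle too, but held no gene of that cycle alone. The citrate synthase gene gltA_2 rose from 38.5 ± 4.51 to 69.1 ± 3.24 CPM (SD, n = 3 in each group), a log2 fold change of 0.84 (edgeR adjusted p = 4.2e-05). The succinate dehydrogenase gene sdhA_1 had a log2 fold change of 0.60 (edgeR adjusted p = 4.5e-04), which is uncertain, as 13.3% of its reads mapped to 1 place and the call was lost with all mapped reads (adjusted p = 0.0538), with the file date as a term (0.133) and within the first file date (0.154), at log2 fold changes of 0.32, 0.34 and 0.35. The remaining calls, named after their values were seen, were fumC (log2 fold change 0.51) and sdhB_1 (1.31, with 4.12% of its reads mapped to 1 place) among those higher and sucA_2 (-0.58) as the lower gene. The calls of sdhB_1 and sucA_2 were lost with the file date as a term (adjusted p = 0.142 and 0.0872), with the optical density as a term (0.161 and 0.0637) and within the first file date (0.109 and 0.117), and that of sdhB_1 also without wild type 3 (0.0553). The log2 fold changes in the first 3 of these fits were 0.74, 0.96 and 0.75 for sdhB_1 and -0.55, -0.56 and -0.53 for sucA_2. With all mapped reads 3 genes of the list were called lower and 3 higher: sdhB_1 stood at 0.30, and sdhA_2 and sdhB_2, of whose reads 13.1% and 3.49% mapped to 1 place, went from -0.07 and -0.15, not called, to -0.35 and -1.14 (adjusted p = 0.0295 and 1.8e-06), so the values of all 4 sdh genes are uncertain. sdhB_2 was also called lower with the file date as a term (-1.06, adjusted p = 0.0208) and within the first file date (-1.05, adjusted p = 0.0249), and gltA_1, at 0.30 and not called over all genes (adjusted p = 0.0537), was called higher with the date term (0.47, adjusted p = 0.0422) and when adjusted over the list alone (0.0263); both were named after their values were seen. Camera did not separate the list from other genes (adjusted p = 0.198), except without mutant 1 (0.0455). Of 4 methylcitrate cycle genes, which serve propionate breakdown, prpD rose (log2 fold change 0.35, edgeR adjusted p = 0.0105) and prpB_2 on pBPHY01 fell (-1.46, edgeR adjusted p = 3.1e-05). prpB_1, named after its value was seen, rose by 0.39 on the log2 scale, and prpE was not called. The median of this list was 0.16 and its mean -0.19. The prpD call was lost without wild type 3 (adjusted p = 0.0674), with the file date as a term (0.169), with the optical density as a term (0.0621) and within the first file date (0.204), at log2 fold changes of 0.33, 0.30, 0.35 and 0.31. That of prpB_1 was lost with the file date as a term (0.166), within the first file date (0.199) and without wild type 1 (0.0864), wild type 3 (0.115), mutant 1 (0.0592) or mutant 2 (0.1001), at log2 fold changes between 0.27 and 0.41.

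Among genes of nitrogen metabolism, 2 of 4 members of the nitrogen regulation list were lower and none higher (1 higher and 2 lower when adjusted over the list alone). By symbol the list held only glnQ, glnP, glnH and gltD. None of these encodes a regulator, so nitrogen regulation itself was not tested. The gene higher over the list alone was glnQ, named after its values were seen. Its log2 fold change was 1.11 (edgeR adjusted p = 0.0385 over the list alone and 0.0907 over all genes). glnP, at -0.31, was not called. gltD, which encodes the small subunit of glutamate synthase, fell from 1208 ± 233 to 833 ± 64.7 CPM (SD, n = 3 in each group), a log2 fold change of -0.54 (edgeR adjusted p = 0.00342). glnH, a glutamine-binding transport protein gene, fell from 7.09 ± 1.04 to 3.47 ± 0.0940 CPM, a log2 fold change of -1.03 (edgeR adjusted p = 0.00987). The glnH call was lost without wild type 3 (adjusted p = 0.0633), and both calls were lost with the file date as a term (gltD 0.122, glnH 0.0935), with the optical density as a term (0.295 and 0.115) and within the first file date (0.186 and 0.0989). The log2 fold change of glnH stayed near its size in these fits (-1.07, -0.96 and -1.06, and -0.90 without wild type 3), and that of gltD was -0.46, -0.22 and -0.45. Of 3 urease genes ureA was lower (log2 fold change -0.49, chosen after its value was seen), a call that was lost with the file date as a term (adjusted p = 0.310), with the optical density as a term (0.310), within the first file date (0.323) and without wild type 3 (0.200), mutant 2 (0.0600) or mutant 3 (0.166), at log2 fold changes between -0.53 and -0.36. Neither of 2 nifH copies was called by edgeR, DESeq2 or voom, or passed an unadjusted p of 0.05, and only 8.57% and 8.21% of their reads mapped to 1 place. Their log2 fold changes were 1.66 for nifH_1 and 0.11 for nifH_2, so a change is not excluded.

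**Figure D2:**
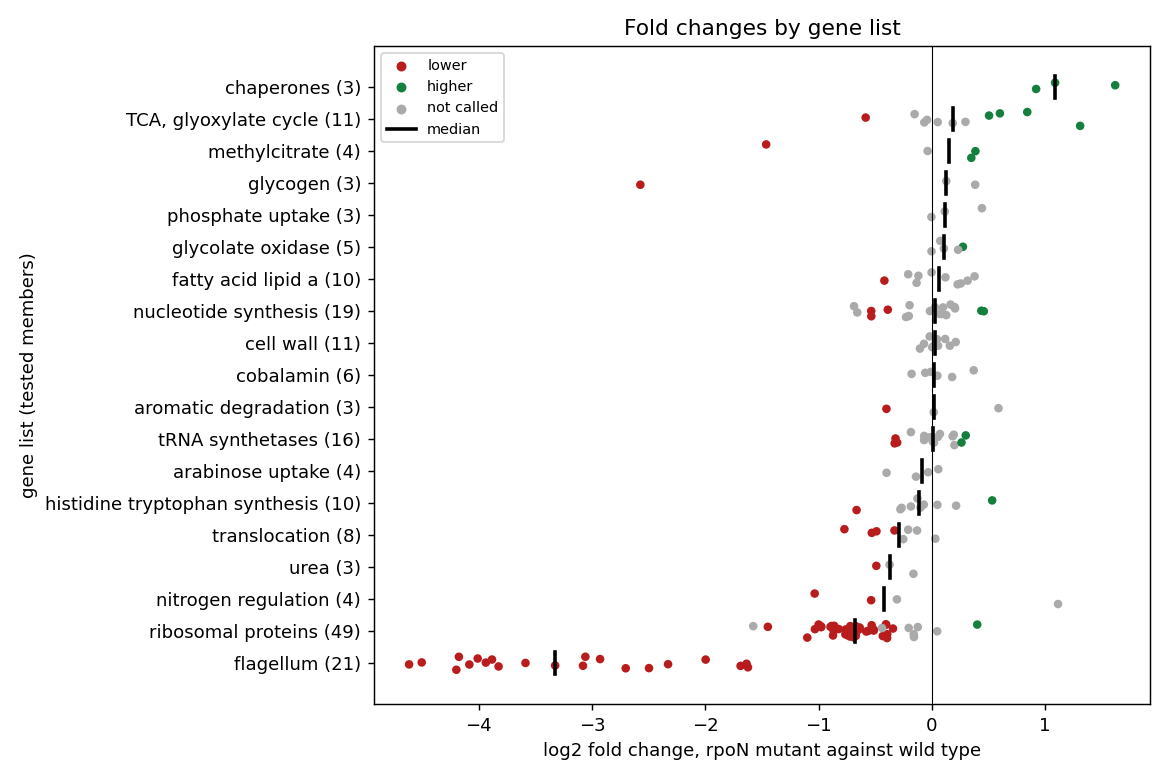
Log2 fold changes of the rpoN mutant against the wild type for single genes (points) in each gene list with at least 3 tested members, with the list median as a black bar and the number of tested members in parentheses. Flagellar genes lie furthest to the left, with a median of -3.33, and chaperone genes furthest to the right, with a median of 1.09; the medians of the tRNA synthetase and cell wall lists fall below 0 with library totals in place of TMM scaling.

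Called genes lay side by side more often than under permutation. Runs of at least 4 neighbouring tested genes changed in the same direction held 521 of the 1978 called genes (26.3%), in 36 runs of higher and 50 runs of lower genes. The mean over 1000 permutations of the calls was 16.3 genes (SD 7.93, highest 44; permutation p = 0.001, the smallest they can give). Within the first file date, runs held 189 genes. Regions described here were chosen after their values were seen. The named flagellar genes lay in a region of chromosome 1 from 3285418 to 3336445, where 43 of 49 tested genes were lower and 6 were not called. On chromosome 1 from 1183125 to 1215127, 23 of 24 tested genes were higher, with a median log2 fold change of 2.51 over the region, a 5.70-fold increase. On pBPHY01 from 503533 to 536714, 24 of 26 tested genes were lower, with a median of -1.41. All 14 tested genes on chromosome 2 from 1014564 to 1042049 were lower, with a median of -1.84. On pBPHY01 from 548682 to 586863, 28 of 33 tested genes were higher, with a median of 0.98, and this stretch includes Bphy_6013 and Bphy_6014. A run of 7 lower genes on chromosome 2 (2469795 to 2478307) included the glycogen synthase gene glgA_2, which fell from 42.9 ± 2.11 to 7.22 ± 0.708 CPM (SD, n = 3 in each group), a log2 fold change of -2.57.

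**Figure D3:**
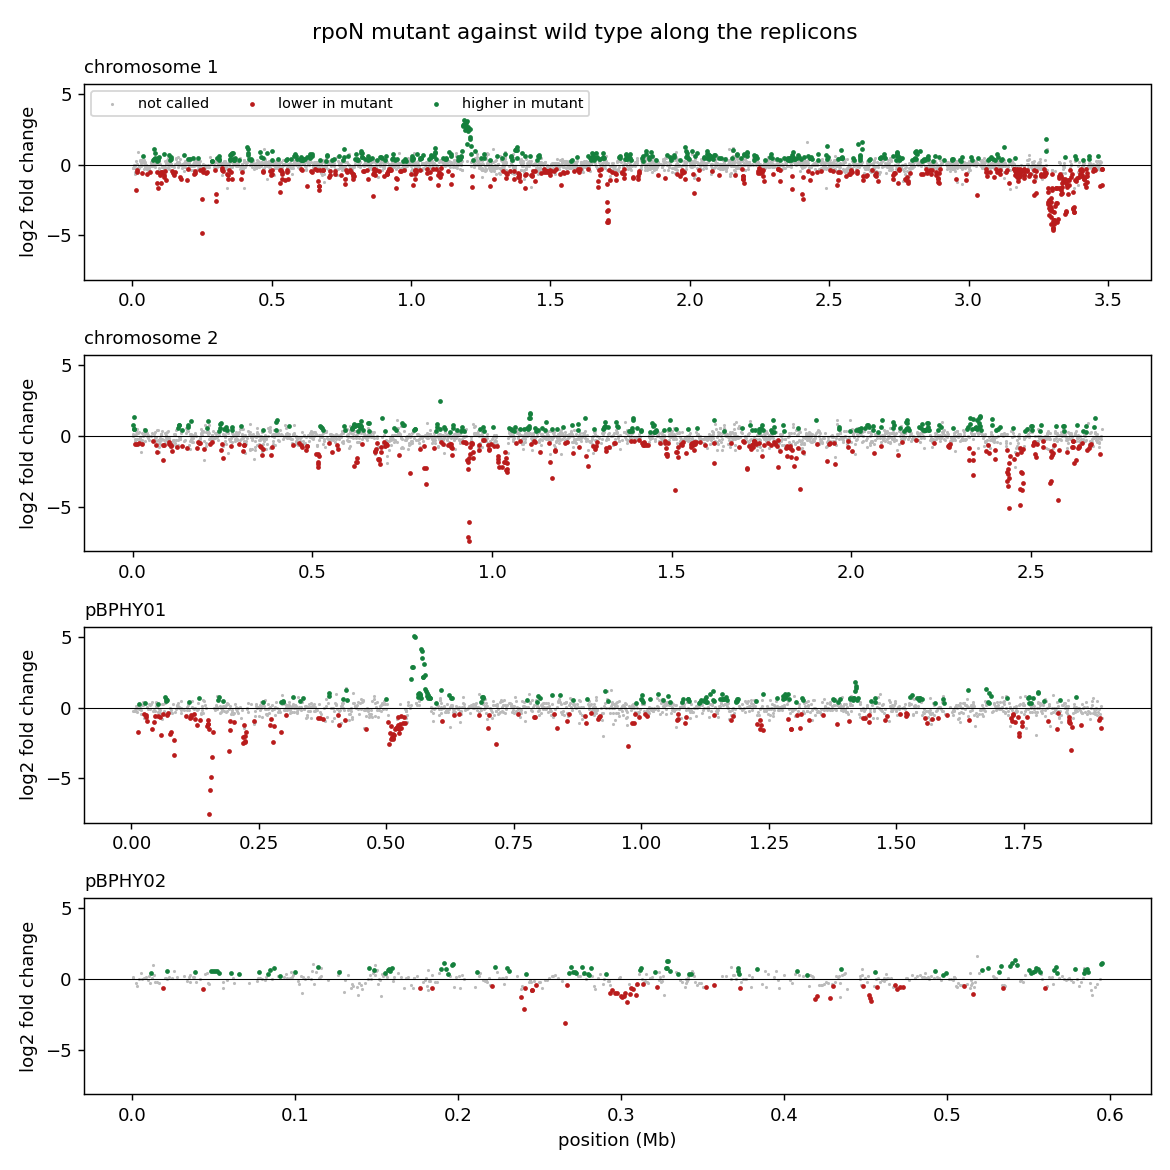
Log2 fold change of each tested gene in the rpoN mutant against the wild type (vertical axis) by position in Mb (horizontal axis) on the 4 replicons, with higher genes in green, lower genes in red and genes not called in grey. The flagellar region stands near the right end of chromosome 1, the stretch of 23 higher genes left of its middle, and the largest increases on pBPHY01 next to a stretch of 24 lower genes.

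The replicons differed in their share of called genes. On pBPHY02, 94 of 518 tested genes were higher (18.1%, against 11.9% elsewhere; odds ratio 1.64, Fisher's exact test, two-sided, adjusted p = 2.0e-04 over 8 tests) and 49 were lower (9.46% against 14.3%; odds ratio 0.627, adjusted p = 0.00318). On chromosome 1, 503 of 3060 genes were lower (16.4% against 12.3%; odds ratio 1.41, adjusted p = 2.9e-06). pBPHY01 had fewer lower genes (odds ratio 0.699, adjusted p = 1.2e-04) and fewer higher genes (0.790, adjusted p = 0.0131) than the rest. Higher genes were somewhat more frequent on chromosome 1 (odds ratio 1.18, adjusted p = 0.0233) and less frequent on chromosome 2 (0.827, adjusted p = 0.0203). Among changes of at least 2-fold none of these tests passed, and the odds ratios of chromosome 1 and pBPHY01 crossed 1 (chromosome 1 lower 0.976 and higher 0.818, pBPHY01 lower 1.02 and higher 1.36). The excess of higher genes on chromosome 1 was lost without mutant 2 (odds ratio 1.15), the deficit of higher genes on chromosome 2 without wild type 3 (0.882) or mutant 2 (0.863), and the deficit of lower genes on pBPHY02 without wild type 3 (0.764). Within the first file date, the tests of higher genes on pBPHY02 and of lower genes on chromosome 1 passed and the others did not. Neighbouring genes are not independent, so these p-values are too small.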

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

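The test of the file date was chosen only after the result was seen. The thinning test was written down before its result. RNA genes took 61.68% of all mapped reads in mutant 2 (95% Wilson interval 61.65 to 61.70) and 64.05% in mutant 3 (64.03 to 64.08), above the 55.24 to 56.25% of the wild type. These reads were outside the comparison of genes, and mutant 1, with 55.28%, lay in the range of the wild type. The excess was seen in the libraries of the later file date only, all of them mutant.

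The later file date, which mutant 2 and 3 share, or their lower depth could account for the genes called between the groups. Genes were called between mutant 2 and 3 and wild type 2 and 3 alone (1744 genes) and looked up in the libraries left out, mutant 1 and wild type 1, both of the first date. There, 1597 of them (91.6%) changed in the same direction, and the median change was 0.53 against 0.72 on the log2 scale in the libraries used for the calls, a ratio of 0.743. This argues against the date as the whole cause. After thinning all libraries to the smallest total, 1874 genes were called, a ratio of 0.947 to the number as deposited, which argues against depth. A part played by the date in single genes stays open, since mutant 1 is the lone mutant library of the first date, and its own deviation cannot be separated from that of the date.

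The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. The real split gave 1978 called genes, 487 with at least 2-fold change, 521 in runs and 7 replicon tests, and the highest of the other splits gave 0 for each by edgeR, with 91 to 184 genes at an unadjusted p under 0.05; 1 split, the real one, was as large in each case. For gene lists the real split gave 2 and the highest other split 3, and 6 of the 10 splits gave as many. Camera with its preset correlation called flagellar and ribosomal protein lists in regroupings of the same libraries too. Each regrouping puts 2 libraries of 1 genotype with 1 of the other on a side, so part of the genotype difference remains in it. That difference also adds to the spread within each side, so counts of called genes near 0 were to be expected there. The contrast with the real split therefore does not show what chance gives.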

How the results depend on the processing

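The 4 alternatives on all mapped reads, on the first file date, on thinned counts and on genes of at least 300 bases were chosen after seeing the data; the others were planned. The tests of the promoter motif and their alternatives were not run. Counts of higher and lower genes moved by over 1.5 times with the file date as a term (509 and 544), with the optical density as a term (549 and 605), within the first file date (450 and 459) and at an adjusted p under 0.01 (572 and 659). The last leaves fewer calls by construction. The fits on the date compare mutant 1 with the wild type, and that on the density compares the mutant with wild type 1. Resting on a lone library also leaves fewer calls by itself, and any further cause was not tested. Of the 1978 calls, 996 were kept in the same direction with the date term, 1068 with the optical density and 868 within the first date. Without single libraries, 732 to 885 genes were higher and 759 to 971 lower, with 108 to 123 and 338 to 418 at 2-fold. In the other fits 694 to 1000 were higher and 961 to 1214 lower. No call changed sign in any of these fits, except 1 gene with all mapped reads. The median of all genes was -0.03 with TMM and -0.09 with library totals.

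With the replicate number as a block, 885 genes were higher and 997 lower, and 1836 calls were kept. Same-numbered libraries did not deviate together (correlations -0.006, 0.004 and -0.039), and no library correlated best with its own number. The numbers were therefore not taken as pairs. Among the named genes Bphy_6013 and Bphy_6014 lost their calls under the block (adjusted p = 0.0806 and 0.0895), as did ureA, chosen after its value was seen (0.0560), at log2 fold changes of 5.41, 5.31 and -0.49.

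For gene lists, the calls of flagellar and ribosomal protein genes were lost with an estimated correlation (both adjusted p = 0.447), and the translocation list passed with fry (0.0307), which does not compare it with other genes. Without single libraries, the adjusted p of the tricarboxylic acid list was 0.0455 to 0.544 and that of the translocation list 0.0455 to 0.290, both lowest without mutant 1. Within the first file date 9 flagellar and 28 ribosomal protein genes were lower and 2 genes of the tricarboxylic acid cycle higher. With the date term 0 ribosomal protein genes were higher. The count was also 0 with genes of at least 300 bases, a fit that leaves shorter genes untested. With all mapped reads 3 genes of the tricarboxylic acid cycle were lower. Runs of at least 6 held 272 genes, runs within the first file date 189, and runs without single libraries 377 to 459.

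Odds ratios turned at 2-fold for chromosome 1 higher (0.818) and lower (0.976) and pBPHY01 higher (1.36) and lower (1.02). They were no longer past the threshold there for chromosome 2 higher (0.904), pBPHY02 higher (1.20) and pBPHY02 lower (0.588). The same was so within the first file date for chromosome 1 higher (1.17), chromosome 2 higher (0.836), pBPHY01 higher (0.774), pBPHY01 lower (0.742) and pBPHY02 lower (0.622). The cause was not tested. Without single libraries the odds ratios were 1.15 to 1.31 for chromosome 1 higher (lost without mutant 2), 0.787 to 0.882 for chromosome 2 higher (lost without wild type 3 or mutant 2), 0.839 to 0.999 for chromosome 2 lower (passed without wild type 1) and 0.503 to 0.764 for pBPHY02 lower (lost without wild type 3).

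Of the 36 named genes, 10 lost their call with the date term, 12 within the first date and 7 with the optical density, none with another scaling, filter or tool, and none changed direction; with genes of at least 300 bases this covers 34 of them, as groES and rpmI are shorter. In the simulation, where far fewer genes changed than were called in the data, 44.8% of 1.5-fold changes were recovered. The share in the data may differ, but a missing call does not show the absence of such a change.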

Other observations

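The tests of culture density, of the share of genes highest or lowest in wild type 2 and of ribosomal protein genes in mutant 1 were chosen only after the result was seen. Further lists of core functions were assembled from the names in the files, where 26.3% of all tested genes were called. Of 16 aminoacyl-tRNA synthetase genes 2 were higher and 3 lower: metG rose by 0.30 on the log2 scale (edgeR adjusted p = 0.0274) and lysS fell by 0.33 (0.0269). The lysS call was lost without mutant 2 (0.196), mutant 3 (0.0752), wild type 2 (0.119) or wild type 3 (0.132), and that of metG without mutant 1 (0.0630), mutant 3 (0.0917) or wild type 3 (0.0695). Both were lost with the file date (lysS 0.401, metG 0.155) or the optical density as a term (0.451 and 0.0703) and within the first file date (0.482 and 0.184). In these fits metG kept its size (0.31, 0.35 and 0.33), and lysS was at -0.22, -0.17 and -0.20. Of 19 nucleotide synthesis genes 2 were higher and 3 lower, among them the kinase genes pyrH and ndk, which both fell by 0.53 (edgeR adjusted p = 3.5e-04 and 3.9e-04); the median was 0.03 and the mean -0.08. The ndk call was lost with the file date as a term (0.0631, at -0.39), and within the first file date those of ndk (0.124, at -0.37) and pyrH (0.0620, at -0.47) were lost and no gene of the list was called. gmk, named after its values were seen, was called lower with the date term (-0.46, edgeR adjusted p = 0.0337) but not in the main fit (-0.20, 0.214). Of 10 histidine and tryptophan synthesis genes hisH rose by 0.53 (edgeR adjusted p = 9.0e-04) and hisG fell by 0.66 (1.7e-04), a call that was lost within the first file date (0.0637, at -0.51). Protein translocation genes were lower in 4 of 8 cases, with secG and secF at -0.77 and -0.53 (camera adjusted p = 0.138 for the list, and 0.911 with an estimated correlation). With the file date as a term, and within the first file date, 1 of the 8 was called lower, and the secF call was lost in both (0.0648 and 0.123), at -0.40 and -0.38. Of 10 fatty acid and lipid A genes 1 was lower, lpxB (log2 fold change -0.42), and of 5 glycolate oxidase genes 1 was higher, glcE_1 (0.27), both chosen after their values were seen. These calls were lost with the file date (lpxB 0.0988, glcE_1 0.0720) or the optical density as a term (0.204 and 0.194) and within the first file date (0.162 and 0.103), with lpxB at -0.37, -0.26 and -0.35 and glcE_1 at 0.36, 0.27 and 0.37. That of glcE_1 was lost when adjusted over the list alone (0.0501), with library totals (0.115) and without wild type 1 (0.0593), wild type 3 (0.170), mutant 1 (0.120) or mutant 2 (0.0644) as well, at 0.21 to 0.31.

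No gene was called by edgeR among 11 cell wall, 6 cobalamin, 4 arabinose uptake and 3 phosphate uptake genes; at an unadjusted p under 0.05 the counts were 0, 1, 0 and 1, DESeq2 called 1 cobalamin gene and voom none. Single called genes of small lists, chosen after their values were seen, were atpC of the ATP synthase (log2 fold change -0.65) and paaB of 3 genes of aromatic compound breakdown (-0.40). atpC lay in a run of 9 lower genes on chromosome 1 (3397260 to 3406793), whose other genes carry no symbol. The atpC call was lost with the optical density as a term (0.0538, at -0.43). That of paaB was lost there (0.468), with the file date as a term (0.415), within the first file date (0.434) and without wild type 2 (0.117), wild type 3 (0.120), mutant 2 (0.0749) or mutant 3 (0.180), at -0.41 to -0.23. Of 3 glycogen genes glgA_2 was called, and the list had a median of 0.13 and a mean of -0.69. glgA_1, named after its values were seen, had a log2 fold change of 0.38 and was not called over all genes (adjusted p = 0.0702) or within the first file date (0.0534), but was called higher when adjusted over the list alone (0.0306) and with the file date as a term (0.60, adjusted p = 0.0451).

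Wild type 2 stood apart from wild type 1 and 3 in the flagellar genes, and a biological explanation was not tested, since the labels give none besides density. Culture density could be a cause, as wild type 2 and 3 share an optical density below that of wild type 1, but the median difference from wild type 1 was 0.86 in wild type 2 and -0.06 in wild type 3, a ratio of -0.069, which argues against it. Library scaling is argued against too, as the median difference of wild type 2 from the others was 0.93 on the log2 scale, outside the central 95% of 10000 random lists matched on expression (-0.15 to 0.11). Whether the wild-type libraries vary along the same genes that differ in the mutant cannot be told apart from chance variation of single genes, as the correlation across 7517 genes, which are not independent replicates, was -0.102 (Spearman's rho -0.043), close to the bound set against it, and -0.079 without the flagellar genes. Genes were also called at 2-fold or more in a fit without wild type 2, and those tested with all libraries too were looked up. Of 350 lower genes, 48.6% were highest in wild type 2 among the wild-type libraries and 31.4% lowest there. Outside the flagellar list (329 genes) the shares were 45.3% and 33.4%. Of 112 higher genes, 50% were lowest in wild type 2 and 28.6% highest. Over all genes, 34.4% were highest and 36.2% lowest. A call without wild type 2 favours genes in which wild type 1 and 3 lie close together. That alone puts wild type 2 at an end more often, so the shares of all genes are no like comparison and no conclusion is drawn.

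Ribosomal protein genes are short (median 369 bases), and short genes had fewer reads in mutant 2 and 3, so a loss of short fragments at the later date, or length alone, might explain their decrease. In mutant 1, of the first date, their median difference from the wild type was -0.66 and 43 of 49 lay below every wild-type library, which argues against the later date. The median of -0.68 over the groups lay outside the central 95% of 10000 random lists matched on length (-0.26 to 0.10), which argues against length alone. A lower growth rate or another effect of the mutation stays among the open explanations and was not tested. Short genes themselves (127 genes under 200 bases) had a median difference of -0.27 between mutant 2 and 3 and mutant 1. For genes of at least 1000 bases it was 0.02. The bootstrap interval for short genes, -0.43 to -0.12, does not cover the spread between libraries, as mutant 1 stands alone. The median of short genes lay between the bounds set for and against a loss of short fragments, so the cause cannot be told apart.

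rpmJ and a pair of other genes, of 117 and 114 bases, had 105 to 1067 reads in each library of the first date and 0 in mutant 2 and 3, in all mapped reads as well.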
